A study of Caenorhabditis elegans with 6 samples.

How the data were processed

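Gene expression was measured by RNA sequencing in 6 libraries, 3 of anchor cells and 3 of whole-body cells of wild-type Caenorhabditis elegans. Per the labels' protocols, synchronized larvae were grown at 20 °C on NA22 bacteria. Cuticles were loosened with SDS and DTT, and cells were freed with pronase E at 15 mg/mL and passed through a 5 μm filter. RNA was taken by phenol and chloroform, 8 to 10 ng per sample, and libraries were made with the Ovation RNA-Seq System, which amplifies small amounts of RNA. How anchor cells were separated from other cells is not given in the sources used here. Per the submitters' processing notes, FastQC, Trim Galore, STAR, HTSeq, R 4.0.2 and DESeq2 1.30.1 were used with genome build WBcel235; their versions, where not given here, and the strand setting and annotation release are not given in the sources used here.

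The deposited values are raw counts per gene, whole numbers with no normalization, per the file contents, with a row for each of 46748 gene names and 5 summary rows. The summary rows stayed out of library sizes and tests. As shares of all counts of a library, summary rows included, reads assigned to no gene came to 0.807% to 3.88%. Reads assigned to more than 1 gene came to 0.303% to 0.677%. Gene names were matched to the Ensembl annotation of WBcel235, and 99.0% of the gene rows matched. That annotation may differ in release from the submitters' own. Amplified reads without molecular identifiers are not independent molecules, so precision from depth covers counting error only. At 23279623 to 37501816 gene counts per library, 3 counts correspond to 0.0800 to 0.129 CPM.

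Genes with enough counts were kept by filterByExpr of edgeR 4.0.16, which left 11955. Libraries were scaled by TMM, with factors of 0.674 to 0.889 in anchor cells and 1.17 to 1.66 in whole-body cells. Under that scaling the median log2 fold change of all tested genes was -0.12, and it was -0.94 with libraries scaled by their totals alone. Anchor cells were compared with whole-body cells by edgeR's robust quasi-likelihood F test in R 4.3.3, with the group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM values use the TMM scaling and are given as mean ± SD of 3 libraries. Log2 fold changes are given with an SE derived from the test, the absolute change divided by the square root of its F value. The same step was tested on simulated counts for 11955 genes with 200 genes changed by known folds. It recovered 4.48% of genes changed 4-fold, 38.8% of those changed 16-fold and 83.3% of those changed 64-fold, with 4 false calls among 88. The simulation gave both groups the same spread, whereas the real anchor cell libraries were less alike than the whole-body libraries. It therefore did not test the step under unequal spread.

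Before the data were examined, 35 gene lists were fixed, covering anchor cell markers, invasion effectors, actin regulators, basement membrane, matrix proteases, Notch and guidance genes, ribosomes and translation, secretion, energy, cell cycle, histones, stress and markers of the other cell types a larva holds. They resolved to 1283 genes in the files, 44 of them under another name, and 52 members found no match, most of them ribosome biogenesis genes. Lists with at least 3 tested genes, 34 in all, were tested by camera in limma 3.58.1 with its preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, and with an estimated correlation none of the lists passed. The median, the mean and camera's direction differ in sign for matrix proteases, vacuolar ATPase, glycolysis, heat shock and stress, seam cells, and netrin and guidance receptors, none of which passed. Counts adjusted over the list alone use the same p-values with Benjamini-Hochberg adjustment within the list. The ribosome, translation and secretion lists were included knowing that the study of these libraries concerns ribosome biogenesis.

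The named genes follow a rule also fixed before the data were examined. It takes every anchor cell marker and each invasion effector that passed. It adds the 10 largest rises and 8 largest falls among genes past the threshold with a mean of at least 20 CPM in the higher group, no overlap between the groups and a gene-class symbol. It then takes up to 2 genes per direction with the smallest adjusted p from each other list, and the 3 genes with the most counts in each group. The rule named 66 genes.

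No library duplicated another: the chi-square per degree of freedom between libraries of a group was 92.7 or more. Alternatives were upper-quartile and DESeq2 size factor scaling, library totals alone, DESeq2 1.42.0, limma voom, no filter, at least 10 CPM in at least 3 libraries, the replicate number as a block, no rRNA or mitochondrially encoded genes, a test against a fold of 1.5, and each library left out in turn. Limma voom with sample weights was added after the data were seen, because anchor cell replicate 1 stood apart. Reads were not analysed here.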

Results

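The anchor cell is the uterine cell of the Caenorhabditis elegans larva that breaches the basement membrane between gonad and epidermis and so begins the connection of uterus and vulva. RNA from anchor cells (n = 3 libraries) and from cells of the whole body (n = 3 libraries) was sequenced, both taken from wild-type larvae in the middle of the L3 stage, when the vulval precursor P6.p had divided into 2 cells. The libraries held 23279623 to 37501816 counts on genes. Anchor cell replicates 1, 2 and 3 had counts on 16990, 11508 and 11073 genes, and whole-body replicates 1, 2 and 3 on 21246, 22216 and 17185 genes. Across genes, which are not independent replicates, Spearman's rho was 0.763 to 0.795 between anchor cell libraries, 0.888 to 0.955 between whole-body libraries and 0.689 to 0.771 across the groups.

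Ribosomal RNA took a large part of every library, and mitochondrial transcripts took more of the anchor cell libraries. Nuclear rRNA made up 18.4%, 42.9% and 33.5% of gene counts in anchor cell replicates 1, 2 and 3 and 52.5%, 32.1% and 54.3% in whole-body replicates 1, 2 and 3. Mitochondrial rRNA made up 15.2% to 20.3% of anchor cell counts and 3.59% to 5.58% of whole-body counts. Mitochondrially encoded mRNA made up 27.8% of counts in anchor cell replicate 1, 7.76% and 8.36% in replicates 2 and 3, and 1.07% to 1.59% in the whole-body libraries. That share takes in every gene of the mitochondrial genome other than its rRNA genes. Between 9470948 and 23706440 counts per library fell on all other genes.

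**Figure D1:**
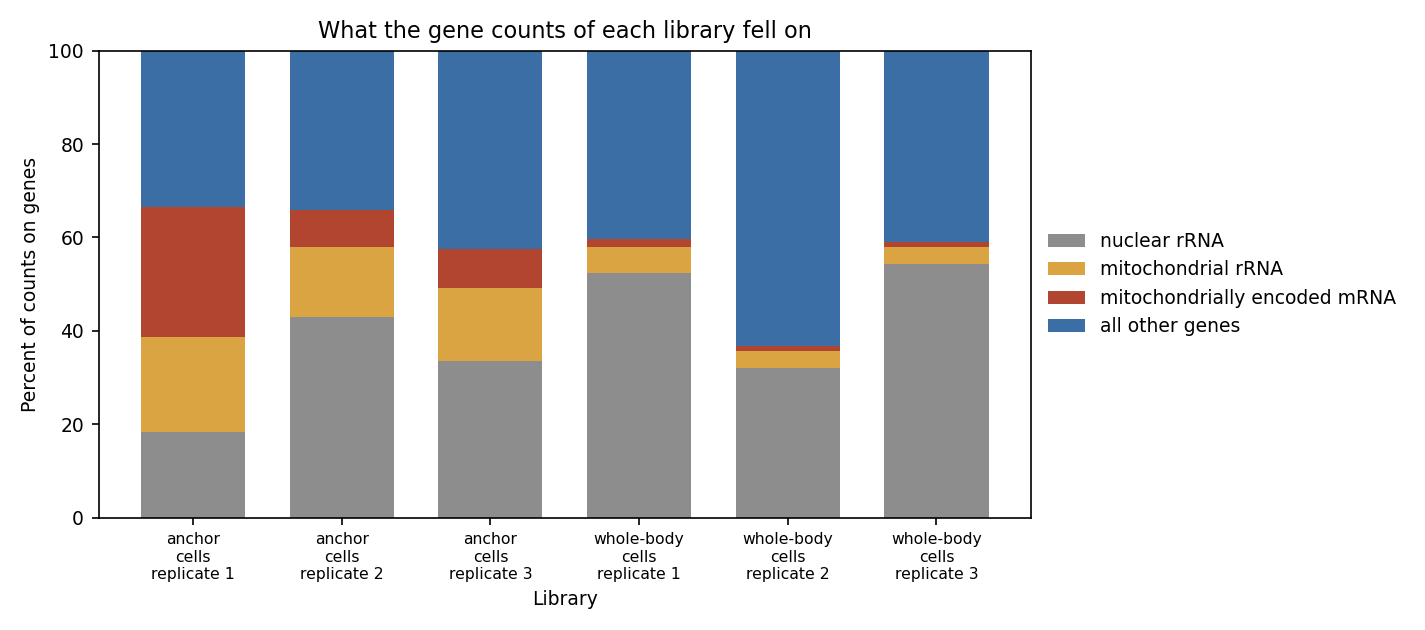
Percent of gene counts in each of the 6 libraries (bars, vertical axis from 0 to 100) that fell on nuclear rRNA, mitochondrial rRNA, mitochondrially encoded mRNA and all other genes. Mitochondrially encoded mRNA reaches 27.8% in anchor cell replicate 1 and at most 1.59% in a whole-body library. Its share takes in every mitochondrial gene other than the rRNA genes.

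The comparison asked which genes were higher or lower in anchor cell libraries than in libraries of whole-body cells, all passed through a 5 μm filter. Of 10 known anchor cell markers 7 rose, led by the nuclear receptor gene nhr-67, 163 ± 89.1 CPM in anchor cells against 1.37 ± 0.707 CPM in whole-body cells (SD, n = 3 each). All 12 tested protein genes of the mitochondrial genome rose, and 14 of 92 tested cuticle collagen genes rose while none fell. Of 30 tested muscle genes 6 fell, as did 6 of 39 tested germ line genes. Of 11955 genes tested, 240 rose and 125 fell with edgeR's quasi-likelihood test at an adjusted p threshold of 0.05. All 365 differed by at least 2-fold, the smallest by 1.58 on the log2 scale, and had no overlap between the groups' libraries. Over all tested genes, 35.6% had no such overlap, where chance gives 10%. Of these genes, 1485 were higher and 2772 lower in anchor cells, the reverse of the balance among the calls. Of the calls, 65.8% were rises, against 20.9% when libraries were scaled by their totals alone. Other tests also gave another split, with 33.5% rises by DESeq2, which ran on 26845 genes, and 26.6% by limma voom. The counts also changed when single libraries were left out, which leaves fewer libraries to estimate each gene's variability. Without anchor cell replicate 1 they were 966 and 1156, without anchor cell replicate 2, 102 and 50, without whole-body replicate 1, 80 and 28, without whole-body replicate 2, 106 and 26, and without whole-body replicate 3, 31 and 7.

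Of 10 genes fixed as anchor cell markers, 7 rose and none fell, and 8 rose when adjusted over the list alone. Their median log2 fold change was 3.25 (camera adjusted p = 5.27e-14, and adjusted p = 0.0951 with an estimated correlation). The largest rises were of nhr-67 (chromosome IV, 11169748 to 11174791), by 6.88 ± 0.72 on the log2 scale (SE), egl-43 (chromosome II, 9955185 to 9963020), a zinc finger regulator of invasion, by 5.19 ± 0.62, and the bHLH gene hlh-2 (chromosome I, 7190788 to 7193920), by 4.90 ± 0.53; their edgeR adjusted p values were 0.00321, 0.00569 and 0.00321. The Notch ligand gene lag-2 rose by 4.42, the zinc finger gene lin-29 by 3.74, the cadherin gene cdh-3 by 2.75 and the Fos transcription factor gene fos-1 by 2.69. The remaining 3 markers did not pass. The EGF gene lin-3, which signals to the vulval precursors, differed by 1.73 (edgeR adjusted p = 0.0941). The hemicentin gene him-4 differed by -0.72 (edgeR adjusted p = 0.355), and the metalloprotease gene zmp-1 was low in both groups at 1.02 ± 0.439 against 0.665 ± 0.365 CPM (SD, n = 3 each; edgeR adjusted p = 0.822). Of the 7 calls, 4 stayed past the threshold without anchor cell replicate 2, 6 without anchor cell replicate 3, 5 without whole-body replicate 1 or 2, and 4 without whole-body replicate 3.

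**Figure D2:**
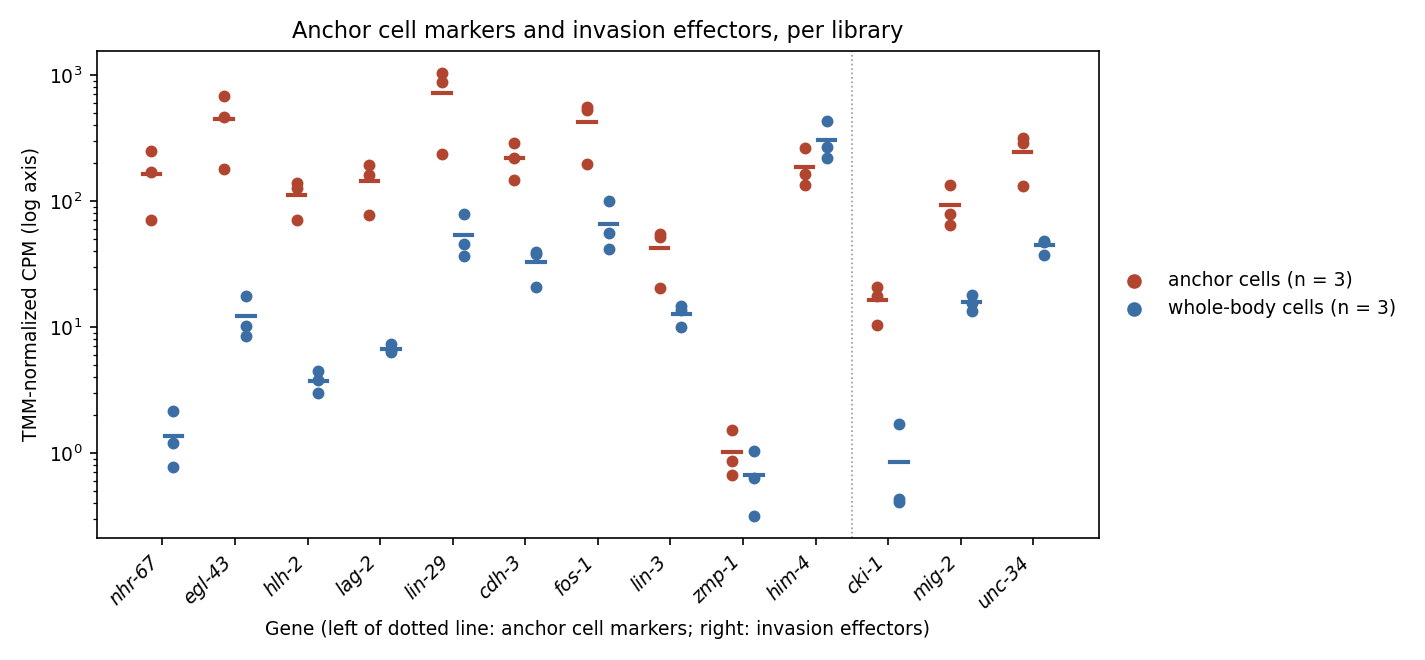
TMM-normalized CPM on a log axis for 10 anchor cell markers and the 3 invasion effectors past the threshold; each point is a library and each bar the mean of 3. For nhr-67, anchor cell means are 163 CPM and whole-body means 1.37 CPM, while him-4 and zmp-1 overlap between the groups.

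Among genes of the invasion machinery a few rose. Of 11 tested invasion effectors, 3 rose and none fell, and 5 rose and 1 fell when adjusted over the list alone. The list's median log2 fold change was 1.16 (camera adjusted p = 0.000978, and adjusted p = 0.181 with an estimated correlation), and the list did not pass with only genes of at least 10 CPM in at least 3 libraries (camera adjusted p = 0.143). The 3 were unc-34, an Enabled homolog that promotes actin growth, by 2.47 ± 0.45 (SE), the Rac-like GTPase gene mig-2, by 2.56 ± 0.48, and the cell cycle inhibitor gene cki-1, by 4.27 ± 0.95. None of these 3 calls stayed past the threshold without whole-body replicate 1, 2 or 3, 1 stayed without anchor cell replicate 2 and 2 without anchor cell replicate 3. Among 46 actin regulators, 4 rose and none fell, over all genes and when adjusted over the list alone, and the median was 0.66 but -0.19 with libraries scaled by their totals (camera adjusted p = 0.000978, and adjusted p = 0.482 with an estimated correlation). The actin median against the whole-body mean was 0.065 in anchor cell replicate 1, 0.66 in replicate 2 and 0.84 in replicate 3. The genes that rose included the non-muscle myosin gene nmy-1, up by 2.37, and arx-3, a subunit gene of the actin-branching complex, up by 2.07. All 4 calls were lost without anchor cell replicate 2 or any of the whole-body replicates, and 1 stayed without anchor cell replicate 3.

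The basement membrane, protease, Notch and guidance lists did not pass as lists, though the Notch list passed without anchor cell replicate 3 (camera adjusted p = 0.0301) and the basement membrane list without whole-body replicate 3 (camera adjusted p = 0.0388). Of 26 basement membrane genes, 1 rose and 1 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.231). These were the nidogen gene nid-1, 299 ± 97.5 against 35.8 ± 8.73 CPM (SD, n = 3 each), and the F-spondin gene spon-1, which fell by 4.51 on the log2 scale. The fold of spon-1 is uncertain, as it had 60 counts over the 3 anchor cell libraries. Of the nid-1 and spon-1 calls, 1 stayed without anchor cell replicate 2 or whole-body replicate 1 or 2, and none without whole-body replicate 3. None of 19 matrix proteases passed edgeR's test, over all genes or when adjusted over the list alone (camera adjusted p = 0.737); at an unadjusted p under 0.05, 4 were higher and 2 lower, DESeq2 called 1 rise and 2 falls, and limma voom 2 falls with or without sample weights. In the Notch pathway 2 of 19 genes rose, lag-2 and the coactivator gene sel-8 (3.36), with the same 2 when adjusted over the list alone (camera adjusted p = 0.274), and 1 of the calls stayed without whole-body replicate 3. Among 28 netrin and guidance receptor genes 2 rose, the ephrin gene efn-2 by 2.80 and madd-2 by 3.08, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.337). The calls of efn-2 and madd-2 were lost without any of anchor cell replicates 2 and 3 and whole-body replicates 1, 2 and 3.

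The list of ribosomal proteins had a median above 0 and the list of ribosome biogenesis genes one below 0; the difference between the lists was not tested. Cytosolic ribosomal protein genes had a median log2 fold change of 1.15, and 0.31 with libraries scaled by their totals, with 78 of 79 above 0 under the first (camera adjusted p = 4.01e-12, and adjusted p = 0.485 with an estimated correlation). None of the 79 passed edgeR's test singly, over all genes or when adjusted over the list alone; at an unadjusted p under 0.05, 29 were higher and 1 lower, and DESeq2 called 3 rises, limma voom 4 and limma voom with sample weights 15, with no falls. The median against the whole-body mean was 0.028 in anchor cell replicate 1, 1.33 in replicate 2 and 1.70 in replicate 3. Of 63 ribosome biogenesis genes, none rose and 2 fell, and 8 fell when adjusted over the list alone. The biogenesis median was -0.90 (camera adjusted p = 0.00119, and adjusted p = 0.482 with an estimated correlation), and the list did not pass without anchor cell replicate 1 (camera adjusted p = 0.0722). The 2 were rpac-40, which encodes a shared subunit of RNA polymerases I and III and fell by 3.89, and the fibrillarin gene fib-1, which fell by 2.49; both calls were lost without any single whole-body replicate, and 1 was lost without anchor cell replicate 2 or 3. Of 61 mitochondrial ribosomal protein genes none passed, over all genes or when adjusted over the list alone. As a list they did not pass with camera (median -0.012, camera adjusted p = 0.922) but passed downward with fry (fry adjusted p = 0.0383). At an unadjusted p under 0.05, edgeR had 1 of these higher and 5 lower, and DESeq2 called 6 falls, limma voom 2 and limma voom with sample weights 1.

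Of the vesicle coat, endoplasmic reticulum and vacuolar ATPase lists, only the vesicle coat list held genes past edgeR's threshold. These lists were not tested against each other. All 28 tested vesicle coat and trafficking genes had a log2 fold change above 0, with a median of 1.15, and 0.25 with libraries scaled by their totals; 4 rose, 10 rose when adjusted over the list alone, and none fell (camera adjusted p = 1.87e-09, and adjusted p = 0.458 with an estimated correlation). By anchor cell replicate the median was 0.43, 1.197 and 1.59. The small GTPase gene arf-3 reached 1277 ± 512 CPM against 236 ± 42.4 CPM, and the clathrin heavy chain gene chc-1 1361 ± 270 against 400.2 ± 50.6 CPM (SD, n = 3 each). These 4 calls were lost without any single whole-body replicate, and 1 stayed without anchor cell replicate 2 and 2 without anchor cell replicate 3. None of 36 translation factors and none of 38 genes of endoplasmic reticulum translocation and folding passed edgeR's test singly, over all genes or when adjusted over the list alone. At an unadjusted p under 0.05, 6 translation factors were higher and 1 lower, and 4 reticulum genes were higher and 1 lower. DESeq2 called 2 rises in each list, limma voom 1 in each, and limma voom with sample weights 3 and 2. Their medians were 0.74 and 0.31, and -0.11 and -0.60 with libraries scaled by their totals. Against the whole-body mean, anchor cell replicates 1, 2 and 3 had medians of -0.36, 0.89 and 0.74 for translation factors and -0.067, 0.24 and 0.71 for the reticulum list. The translation list had a camera adjusted p = 0.00250 and an adjusted p = 0.565 with an estimated correlation. The reticulum list had a camera adjusted p = 0.0406 and an adjusted p = 0.643 with an estimated correlation, and did not pass without anchor cell replicate 3 (camera adjusted p = 0.322) or whole-body replicate 1 (camera adjusted p = 0.0787). Nor did it pass with upper-quartile scaling (camera adjusted p = 0.115), library totals (0.640) or genes of at least 10 CPM in at least 3 libraries (0.965). The ribosome, translation and secretion lists were chosen knowing that the study of these libraries concerns ribosome biogenesis, so they are not independent evidence of a direction. None of 20 vacuolar ATPase genes passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.353); 2 were higher in edgeR at an unadjusted p under 0.05, and DESeq2 and limma voom called 0. That list passed without whole-body replicate 2 (camera adjusted p = 0.0259).

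Genes of the mitochondrial genome rose. All 12 of its tested protein genes did so, also when adjusted over the list alone, with a median log2 fold change of 4.44 (camera adjusted p = 4.44e-28, and adjusted p = 0.181 with an estimated correlation). An example is nduo-2, a subunit of respiratory complex I, at 1069 ± 256 against 49.2 ± 29.2 CPM (SD, n = 3 each). All 12 stayed past the threshold without any single library except whole-body replicate 3, without which 4 did. The mitochondrial small subunit rRNA (MTCE.7) rose by 3.78 ± 0.58 and the large subunit rRNA (MTCE.33) differed by 2.04 ± 0.50 (SE; edgeR adjusted p = 0.0121 and 0.0594). The rRNA with the most counts, rrn-3.1, differed by 0.27 ± 0.56 (edgeR adjusted p = 0.819) and by -0.55 with libraries scaled by their totals; it stands in a repeat whose copies can share reads, so its count is uncertain. Of 40 nuclear oxidative phosphorylation genes 1 rose, the ATP synthase gene atp-5 (2.42), over all genes and when adjusted over the list alone, and its call was lost without any single library other than anchor cell replicate 1. That list's median was 0.70, and -0.17 with libraries scaled by their totals (camera adjusted p = 0.0111, and adjusted p = 0.560 with an estimated correlation), and it did not pass without anchor cell replicate 3 (camera adjusted p = 0.0833). Against the whole-body mean it was -0.15, 0.79 and 1.05 in anchor cell replicates 1, 2 and 3. None of 20 glycolysis genes passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.737); in edgeR 1 was higher and 1 lower at an unadjusted p under 0.05, and DESeq2 and limma voom called 0.

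The cell cycle list had a median below 0 and the histone list one above 0. Of 45 cell cycle genes, 1 rose and 2 fell, and 2 rose and 12 fell when adjusted over the list alone; the median was -1.21 (camera adjusted p = 0.000328, and adjusted p = 0.287 with an estimated correlation). The replication origin gene orc-1 fell, to 5 counts over the 3 anchor cell libraries against 1014 over the whole-body libraries, which is too few for an exact fold. The mitotic kinase gene plk-1 fell by 3.37, while the survivin homolog gene bir-1 rose by 2.48. These 3 calls were lost without any single whole-body replicate, and 1 stayed without anchor cell replicate 2 or 3. Of 37 histone genes, 3 rose and none fell, and 4 rose and 1 fell when adjusted over the list alone; the median was 1.36 (camera adjusted p = 0.000760, and adjusted p = 0.600 with an estimated correlation). The list did not pass without anchor cell replicate 2 (camera adjusted p = 0.0537), and its median was -0.54 in anchor cell replicate 1 against 2.38 and 1.29 in replicates 2 and 3. The replicated histone genes have near-identical copies, so the values of his-41 (3.25) and his-37 (3.05) are uncertain, and no histone call stayed without anchor cell replicate 2 or whole-body replicate 3. Of 20 heat shock and stress genes 1 fell, the mitochondrial chaperone gene hsp-60, at 78.5 ± 8.51 against 388 ± 39.1 CPM (SD, n = 3 each), over all genes and when adjusted over the list alone (camera adjusted p = 0.557); that call was lost without anchor cell replicate 2 or whole-body replicate 3.

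Some markers of germ line, muscle and intestine fell in anchor cells. Of 39 germ line genes, none rose and 6 fell, and 2 rose and 18 fell when adjusted over the list alone, with a median log2 fold change of -2.92 (camera adjusted p = 7.43e-09, and adjusted p = 0.181 with an estimated correlation). The Piwi gene prg-1 (chromosome I, 7585329 to 7588367) was at 2.13 ± 1.44 against 111.65 ± 30.8 CPM and the Argonaute gene wago-1 at 1.27 ± 0.485 against 38.3 ± 9.17 CPM (SD, n = 3 each). Only 2 sperm genes had enough counts to test; neither passed over all genes and both fell when adjusted over the list alone, and the list was too small for camera. Both had an unadjusted p under 0.05 in edgeR and were called by DESeq2 and by limma voom, though not with sample weights. Of 30 body wall muscle genes, none rose and 6 fell, and 20 fell when adjusted over the list alone, with a median of -1.55 (camera adjusted p = 4.72e-09, and adjusted p = 0.269 with an estimated correlation). The troponin I gene unc-27 was at 396 ± 7.92 against 2302 ± 686 CPM (SD, n = 3 each), and the calsequestrin gene csq-1 fell by 3.18. Of 39 intestinal genes 2 fell, also when adjusted over the list alone, the transporter gene pgp-1 (-4.22) and the intermediate filament gene ifc-2 (-2.22). The intestinal median was -1.38 (camera adjusted p = 0.00542, and adjusted p = 0.570 with an estimated correlation), and the list did not pass without anchor cell replicate 1 (camera adjusted p = 0.321). Without whole-body replicate 3, 1 of the 6 germ line calls and none of the muscle and intestinal calls stayed, and without anchor cell replicate 2, 5 germ line, 1 muscle and no intestinal calls did. Without whole-body replicate 1 or 2, 4 germ line, 2 muscle and no intestinal calls stayed, and without anchor cell replicate 3, 6, 3 and 1 did. None of 21 pharynx genes passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.672); in edgeR 3 were higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 1 rise, limma voom 0 and limma voom with sample weights 1 fall.

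Cuticle collagens were among the largest rises. Of 92 cuticle collagens, 14 rose and none fell, and 37 rose and 3 fell when adjusted over the list alone; the median was 1.95 (camera adjusted p = 2.31e-13, and adjusted p = 0.362 with an estimated correlation). By library the collagen median against the whole-body mean was 0.50, 2.27 and 2.58 in anchor cell replicates 1, 2 and 3. The collagen gene col-175 was at 56.9 ± 38.5 against 0.195 ± 0.129 CPM and col-38 at 243 ± 153 against 1.52 ± 1.41 CPM (SD, n = 3 each). Of the 14 calls, 9 stayed without anchor cell replicate 2, 10 without anchor cell replicate 3 or whole-body replicate 2, 7 without whole-body replicate 1 and 3 without whole-body replicate 3. Of 38 hypodermis and cuticle genes, 2 rose and none fell, the collagen gene bli-6 (6.69) and dao-4, and 12 rose and 3 fell when adjusted over the list alone. The gene dao-4 was at 1.23, 6.65 and 45.1 CPM in anchor cell replicates 1, 2 and 3, and its 13 counts over the 3 whole-body libraries are too few for an exact fold. That list's median was 0.61, and -0.28 with libraries scaled by their totals (camera adjusted p = 0.000978, and adjusted p = 0.485 with an estimated correlation); 1 of its 2 calls stayed without any single library other than anchor cell replicate 1. Of 10 seam cell genes 1 rose and 2 fell, the GATA factor gene egl-18 (1.98) and the hedgehog-related genes grd-13, with 27 counts over the 3 anchor cell libraries, and grd-10 (-3.32), and 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.754). None of these 3 stayed without whole-body replicate 1 or 3, and 1 stayed without anchor cell replicate 2 or 3 or whole-body replicate 2.

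Markers of the gonad, vulva and nervous system were mixed. None of 48 neuronal genes passed edgeR's test singly, over all genes or when adjusted over the list alone. At an unadjusted p under 0.05, 8 were higher and 3 lower; DESeq2 called 3 rises and 3 falls, limma voom 1 rise, and limma voom with sample weights 2 rises. Their median was 0.65, and -0.16 with libraries scaled by their totals (camera adjusted p = 0.0166, and adjusted p = 0.482 with an estimated correlation), and 0.75, 0.24 and 0.48 in anchor cell replicates 1, 2 and 3 against the whole-body mean. Of 20 vulval precursor genes 2 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone. The 2 were nhr-67, also an anchor cell marker, and the homeobox gene cog-1 (3.13), and the EGF receptor gene let-23 fell by 4.57; 2 of these 3 calls stayed without anchor cell replicate 3, and 1 without anchor cell replicate 2 or any single whole-body replicate. The vulval median was 0.63, and -0.25 with libraries scaled by their totals (camera adjusted p = 0.0252, and adjusted p = 0.269 with an estimated correlation), and the list did not pass without whole-body replicate 1 (camera adjusted p = 0.0505). Against the whole-body mean it was 0.90, 0.021 and 0.23 in anchor cell replicates 1, 2 and 3. Of 11 sheath and distal tip cell genes 1 rose, lag-2, and 2 rose when adjusted over the list alone; the median was 1.21 (camera adjusted p = 0.0185, and adjusted p = 0.269 with an estimated correlation), and the list did not pass without whole-body replicate 2 (camera adjusted p = 0.0507). In anchor cell replicates 1, 2 and 3 the median against the whole-body mean was 0.81, 0.44 and 0.011. Of 22 somatic gonad and uterus genes 4 rose and 1 fell, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.110). That list passed without anchor cell replicate 2 (camera adjusted p = 0.0448), without whole-body replicate 3 (0.0426) and without a filter (0.0101). Among them were cdh-3 and fos-1, and the filamin gene fln-1 fell by 1.83; none of these calls stayed without anchor cell replicate 2 or any single whole-body replicate, and 1 stayed without anchor cell replicate 3. Of 14 glial genes 1 fell, itx-1 by 3.99, and 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.530). Of 11 excretory canal and duct genes 1 rose, exc-9 (4.88), and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.754). The itx-1 and exc-9 calls were lost without anchor cell replicate 2 or whole-body replicate 3, and the itx-1 call also without whole-body replicate 1 or 2. None of 6 coelomocyte genes passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.462); in edgeR 1 was lower at an unadjusted p under 0.05, and DESeq2 and limma voom each called 1 fall, limma voom with sample weights 0.

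**Figure D3:**
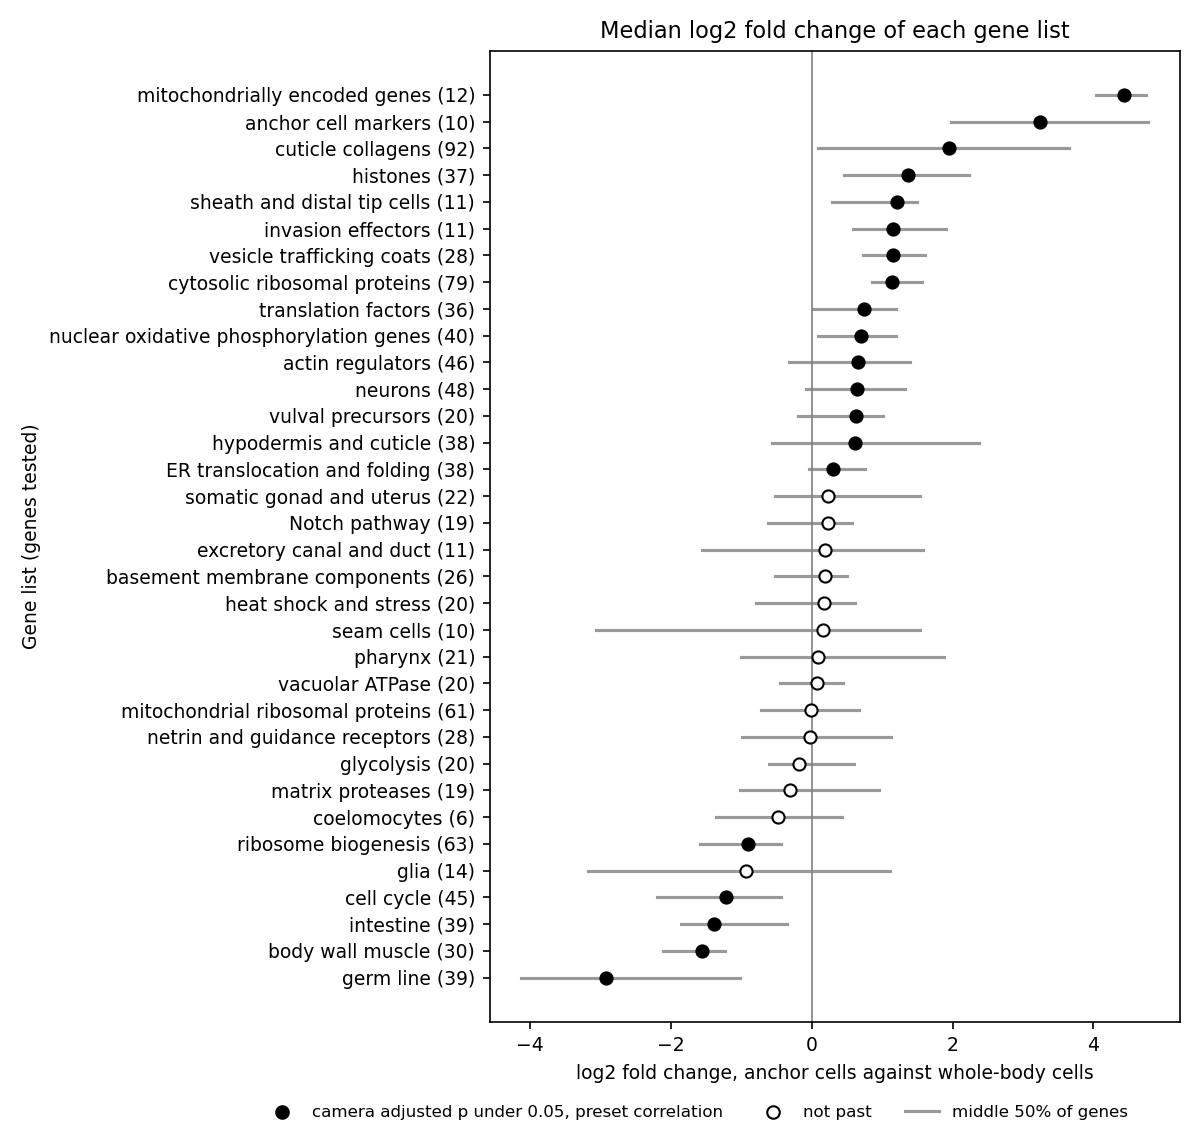
Median log2 fold change of anchor cells against whole-body cells (points) for 34 gene lists, with the middle 50% of each list's genes (lines); filled points passed camera with a preset correlation. The medians run from 4.44 for mitochondrially encoded genes to -2.92 for germ line genes; none of the filled points stayed past the threshold with an estimated correlation, and with libraries scaled by their totals 15 medians above 0 lie below it, 7 of them filled points.

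Several list medians and calls moved under other settings. With libraries scaled by their totals, medians were 0.26 for invasion effectors, 0.49 for histones, 0.97 for cuticle collagens and 0.28 for sheath and distal tip cells, and -1.69 for ribosome biogenesis, -2.06 for cell cycle, -2.36 for body wall muscle and -2.43 for intestine. They were 2.39 for anchor cell markers, 3.74 for mitochondrially encoded genes and -3.76 for germ line. Under that scaling the camera calls of actin regulators (adjusted p = 0.0691), translation factors (0.0866), nuclear oxidative phosphorylation (0.108), neurons (0.0523) and vulval precursors (0.0552) were lost. With only genes of at least 10 CPM in at least 3 libraries, those of actin regulators (camera adjusted p = 0.212), translation factors (0.273), nuclear oxidative phosphorylation (0.273), histones (0.153), hypodermis and cuticle (0.143), neurons (0.102) and vulval precursors (0.273) were lost.

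Among genes past the threshold with a mean of at least 20 CPM in the higher group and a gene-class symbol, the largest rise was of unc-119, a gene known for its role in the nervous system (chromosome III, 10902641 to 10908935). It reached 506 CPM in anchor cell replicate 1, 2604 in replicate 2 and 2123 in replicate 3, against 3.31 ± 1.35 CPM in whole-body cells (SD, n = 3), a difference of 9.04 ± 0.83 on the log2 scale (SE; edgeR adjusted p = 0.00216). The genes rol-1 (7.34), col-38 (7.34) and bli-6 (6.69) were also among the largest under the same limits, with nhr-67 and the splicing factor gene snr-6 (6.61). So were cut-1, grl-23, col-175 and col-63, whose 16, 20, 27 and 26 counts over the 3 whole-body libraries are too few for an exact fold or rank. The SD of cut-1 and grl-23 among anchor cell libraries exceeded the mean. By annotation snr-6 overlaps the neighbouring gene pie-1, so its value is uncertain. The largest falls under these limits were of gld-3 (chromosome II, 7132643 to 7137522), a germ line RNA-binding protein gene, with a log2 fold change of -6.005 ± 1.02 (SE), prg-1 (-5.71) and the acyl-CoA synthetase gene acs-2 (-5.45). They were followed by the germ line stem cell gene sygl-1 (-5.29), mth-1 (-5.06), wago-1 (-4.90), the RNA-dependent RNA polymerase gene ego-1 (-4.88) and pcp-2 (-4.86). Over the 3 anchor cell libraries gld-3, sygl-1 and mth-1 had only 49, 52 and 51 counts, so their folds and ranks are uncertain. The folds of let-23, ego-1, rpac-40, pgp-1, wago-1 and pcp-2 are uncertain too, with 72, 75, 82, 85, 86 and 88 counts there. Of the 61 named calls, 61 kept their side of the threshold without anchor cell replicate 1, 26 without anchor cell replicate 2, 44 without anchor cell replicate 3, 30 without whole-body replicate 1 or 2 and 13 without whole-body replicate 3. Nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.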

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

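No test of this part was planned before the data were seen. Reads that overlapped more than 1 gene entered no gene count. In anchor cell replicate 1 they came to 0.677% of all counts, summary rows included, above the 0.303% to 0.483% of the whole-body libraries. They came to 0.327% and 0.374% in anchor cell replicates 2 and 3, within that range. That share drew attention because it lies outside the gene counts and above every whole-body library. Groups of 3 libraries were not tested for single libraries far from the others.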

How the results depend on the processing

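Limma voom with sample quality weights was chosen after seeing the data. The main counts were 240 rises, 125 falls and 20 lists. Rises and falls were 98 and 372 with libraries scaled by their totals, 799 and 1584 with DESeq2, 390 and 1078 with limma voom, 663 and 1368 with sample weights, 603 and 372 without a filter, 157 and 80 against a fold of 1.5, and 273 and 197 with at least 10 CPM in at least 3 libraries. Rises ranged from 31 to 966 and falls from 7 to 1156 with single libraries left out. The fits with a library left out had equally few libraries, so library number does not account for the spread between them. Each had fewer libraries than the main fit. The variability of each gene was fitted over both groups, and the anchor cell libraries were less alike than the whole-body libraries. A call lost without a library therefore need not rest on that library's own values. The highest counts came without anchor cell replicate 1. Across genes, Spearman's rho of that library was 0.779 and 0.763 with anchor cell replicates 2 and 3. It was 0.762, 0.771 and 0.726 with whole-body replicates 1, 2 and 3. The cause of the spread was not tested. Of the 365 genes, DESeq2 called 239 of the rises and 125 of the falls. Lists past the threshold were 0 with an estimated correlation, 10 with fry (9 shared), 11 with at least 10 CPM, which leaves fewer genes, 14 with library totals, and 18 to 22 with single libraries left out. The list that passed with fry but not camera was that of mitochondrial ribosomal proteins. Lists that passed with camera but not fry included cytosolic ribosomal proteins (fry adjusted p = 0.240), cuticle collagens (0.129) and histones (0.418). With libraries scaled by their totals the log2 fold change was -0.25 for zmp-1 and -0.55 for rrn-3.1, and the list medians were -0.19 for actin regulators, -0.11 for translation factors, -0.60 for endoplasmic reticulum genes, -0.17 for nuclear oxidative phosphorylation, -0.28 for hypodermis and cuticle, -0.16 for neurons and -0.25 for vulval precursors; that scaling moved the median of all genes from -0.12 to -0.94. For rrn-3.1 the values with single libraries left out ran from -0.049 without whole-body replicate 2 to 0.61 without anchor cell replicate 1. Whether the replicate numbers pair the libraries is not given in the sources used here. Each library's deviations from its group mean had correlations of 0.053, -0.032 and -0.0032 within numbers. With 3 libraries per group such values cannot decide it, so pairing stays unknown. The replicate block gave 390 rises, 338 falls and 20 lists. Depth limits genes near 3 counts, such as orc-1 with 5 counts over the anchor cell libraries.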

Other observations

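The gene classes, the neuron, transgene, hypodermis, molting and rRNA tests were chosen after the values were seen; the matched-list test and the splits were written beforehand. Among 135 gene classes with at least 8 tested genes, named by their shared symbol, 12 were higher and 9 lower in anchor cells by camera with a preset correlation. None passed with an estimated correlation. Proteasome regulatory subunit genes (rpn) had a median log2 fold change of 1.42 over 12 genes (camera adjusted p = 0.00157, and adjusted p = 0.708 with an estimated correlation), 11 of them above 0 and none past edgeR's test singly; with libraries scaled by their totals the median was 0.51. The small GTPase genes of vesicle transport (rab) had a median of 1.27 over 18 genes (camera adjusted p = 0.000508, and adjusted p = 0.708 with an estimated correlation), with 1 past the threshold; with library totals the median was 0.35.

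Some other classes had medians below 0. UDP-glucuronosyltransferase genes (ugt) had a median of -1.57 over 48 genes, 43 of them below 0 and 1 past the threshold (camera adjusted p = 0.00304, and adjusted p = 0.708 with an estimated correlation). C-type lectin genes (clec) had a median of -1.40 over 66 genes, with 1 past the threshold, and that 1 rose (camera adjusted p = 0.0353, and adjusted p = 0.708 with an estimated correlation). All 9 tested Pumilio-family genes (puf), some of which are known as germ line translation regulators, were below 0, with a median of -3.53 and 2 past the threshold (camera adjusted p = 0.00486, and adjusted p = 0.708 with an estimated correlation). With libraries scaled by their totals the medians were -2.50 for ugt, -2.38 for clec and -4.23 for puf.

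The gene unc-119 stood 9.04 on the log2 scale above whole-body cells. Neurons among the anchor cells would bring their other transcripts, and the median of 48 neuronal genes was 0.65, which argues against them as the source. A transgene carrying unc-119, a common rescue marker in worm strains, may be a candidate source; the labels give the genotype as wild type. None of the 4 tested genes within 12 kb passed the threshold, and the largest of their values was 2.304, which would hold with or without a transgene, so it cannot be told apart from expression of the gene by the anchor cell.

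The cuticle collagens had a median of 1.95 (95% bootstrap bounds 1.46 and 2.68). Bootstraps and permutations in this paragraph drew genes, which share the same libraries and are not independent replicates. They do not measure the spread between libraries. Hypodermal cells among the anchor cells would raise other hypodermal genes alike, and the 19 non-collagen genes of the hypodermis list had a median of -0.20 (95% bounds -0.51 and 1.18), below the collagen bounds (two-sided permutation p = 0.00313 with 100000 permutations), as did the 14 of them at 20 CPM or more in whole-body cells (-0.21, bounds -0.59 and 0.99). Such cells stay open, because the 14 cuticle collagens past the same 20 CPM limit had a median of 0.22 with bounds of -0.44 and 1.501, which overlap those of the other genes, and because 10 of the 19 are molting genes, outside which the remaining 9 had bounds of -0.84 and 3.49. The labels describe no sort that would remove such cells, and the 19 collagens of the hypodermis list had a median of 2.01 (bounds -0.30 and 2.63). A different point of the molting cycle between the groups may also move collagens, and the 10 molting genes ran from -0.73 to 1.93 with a median of -0.080, which decides nothing because cycling genes move in both directions; neither can be told apart from expression by the anchor cell.

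Cytosolic ribosomal protein genes had a median of 1.15, and 0.31 with libraries scaled by their totals. The load of rRNA and mitochondrial transcripts stays open: the median was 1.18 without those genes, but leaving them out moved the median of all genes only from -0.12 to -0.082, so it tested nothing. All libraries were amplified, and a preference for short transcripts that differed between the groups may contribute. In 10000 lists matched on exon length and expression to the 78 of 79 genes with a length, whose median is 1.16, medians ran from 1.32 to 2.09 over the central 95%. The ribosomal list therefore lay below its matched lists, an outcome written for neither possibility. So neither the load nor the preference can be told apart from a difference in the cells, and the list is not higher than other short, abundant genes. No lists were matched to the cuticle collagens or the histones, whose medians were 1.95 and 1.36, so the preference was not tested for them.

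The 6 libraries can be split into 3 and 3 in 10 ways. The real split called 365 genes and 20 lists, and the highest of the other splits 0 genes and 15 lists. In 1 of 10 splits, the real one, was the count of genes or of lists as large, and 10 splits are too few for a share under 0.05.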
